A study of Homo sapiens with 2 samples.

How the data were processed

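Total RNA from 2 cultures of a human lung cancer cell line was measured on 1-colour Agilent expression arrays, with 1 array for gefitinib-sensitive PC-9 cells and 1 array for gefitinib-resistant PC-9GR cells. The samples were grouped by the phenotype given in the labels. Per the labels' protocols, the RNA was amplified and labelled with Cy3 by an Agilent kit for low RNA amounts, and PC-9GR cells were the survivors of exposure to gefitinib at 0.01, 0.1 and 1 µM, for 1 month at each concentration. Per the file headers, the images were read with Agilent Feature Extraction 10.7.3.1, both arrays lay on 1 slide and were read in 1 scan, and the design was number 039494 with probe coordinates on hg19. The series text names design 028004, and the header was followed here because probe names and coordinates came from the same files.

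The deposited scanner files gave for each of 62976 spots a processed intensity that, per the file headers, had been background-subtracted and spatially detrended but not scaled between arrays. The series value table deposited by the authors held the same linear intensity values for all 62976 rows. It differed from the scanner files by at most 0.499% on the PC-9 array, whose scanner file carries values rounded to 3 significant digits, and by at most 0.000122% on the PC-9GR array. The columns of that table had medians of 16.8 for PC-9 and 14.9 for PC-9GR, and neither a log scale nor centring had been applied. In the PC-9 scanner file 75 gene name cells differed from the PC-9GR file because names such as MARCH6 had been turned into dates, as a spreadsheet does, so gene names were read from the PC-9GR file. Other per-spot flags in the deposited files, which mark a spot as well above background, saturated or an outlier, are yes-or-no values and carry no unit.

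Processed intensities were put on the log2 scale and the 75th percentile over the 61657 non-control spots of each array was subtracted. The spots of a probe were averaged, and then the probes of a gene that were well above background on both arrays were averaged. Probes of Y-linked genes and of the X-inactivation transcripts (237 probes) and all probes for synthetic control RNAs were left out, whereas other genes of the X chromosome were kept. That left 50362 gene probes for 36231 genes, of which 49462 probes had 1 spot and 900 had 10 spots. Spots with an outlier flag on either array were then left out (473 spots), after which 50357 probes remained. Of the 50362 probes, 28041 were named through a RefSeq accession, 2612 through a current symbol, 618 through a unique older symbol, and 19091 kept the name in the file. The design had fixed that every used probe must be well above background on both arrays, and this was read as using only the probes that meet it. No spot was saturated on either array.

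The difference for a gene was its log2 level in PC-9GR minus that in PC-9, and a gene counted as apart at 2-fold or more. With 1 array per line no test between the lines was possible, and no p-value is given. A gene with a probe well above background on 1 array and none on the other was given a lower bound, the bright array's level against the higher of the dim probe's own level and the lowest level among probes well above background on the dim array. It counted when the bound was at least 2-fold. A technical standard error was computed from Agilent's spot error for each probe. Its median was 0.208 on the log2 scale. It rests on Agilent's error value for each spot and not on the spread of replicate spots. For bright genes with 1 probe it was often 0.204, as for MET, AXL and CLDN4. By comparison, the SD of the difference between arrays over replicate spots of a probe had a median of 0.08. The technical SE contains nothing about differences between cultures, RNA preparations or labelling. Signal over background and the number of arrays (2) limit the precision.

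In all, 24 gene lists were fixed before the data were examined. A list with at least 5 members measured on both arrays was placed by the percentile of its median difference among 10000 random lists of the same size, matched on mean level in 20 bins. It was said to stand apart below the 2.5th or above the 97.5th percentile. This places a list among other genes of the same 2 arrays and is no test of the lines. The 95% interval of a list median is the exact order-statistic interval over its members.

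The rule for named genes was also fixed before the data were examined. Among genes with a symbol it took the 15 largest differences in each direction whose probes all differed the same way, and the 8 largest bounds in each direction among genes detected on 1 array only. It also took EGFR, ERBB2, ERBB3, MET, AXL, BCL2L11, CDH1, VIM and ABCB1 whatever their values (1 further gene of this set is not reported here), list members apart by 2-fold or more, and up to the 3 highest and 3 lowest members of each list. Probe positions are those in the files, on hg19. Annotation of exons and untranslated regions on that build was not used here.

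The alternatives were median scaling, quantile normalisation, no scaling, centring on the median over the spots of the labelled spike-in RNAs, the 75th percentile of spots well above background on both arrays, removal of a loess trend on level (span 0.3), normexp background correction of the raw signals (offset 50), and the series value table. Others were no filter and a stricter filter on dim probes, the brightest probe or the median of probes per gene, outlier spots kept, thresholds of 4-fold and 1.5-fold, and random lists not matched on level. Counts over genes with a replicated measurement, removal of a trend on probe GC content and centring on the median of the spike-in probe differences were added after seeing the data. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and R 4.3.3 with limma 3.58.1. They were tested on a simulated pair of arrays with 200 altered genes and the technical spread of replicate spots. Of the genes in the step, 16679 were measured on both simulated arrays. All 44 measured genes altered 4-fold and all 38 altered 8-fold were called apart by 2-fold, as were 42 of 43 altered 2.5-fold and 0 of 49 altered 1.5-fold. Of 16505 unaltered genes 0 were called. The simulated noise had 1 size for all spots, with no isolated bright spots and no variation between cultures, RNA preparations or labellings. The absence of calls was therefore near certain beforehand and gives no rate of false calls for the real arrays.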

Results

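The series compared PC-9, a human non-small cell lung cancer line with an activating EGFR mutation that makes it sensitive to the EGFR kinase inhibitor gefitinib, with PC-9GR, its derivative that survived stepwise exposure to 0.01, 0.1 and 1 µM gefitinib. The comparison asks how the transcriptome of the resistant cells differs from that of the cells they came from. Each line was hybridised to 1 Agilent array, so the differences below have no replicate check and describe these 2 RNA samples. Of 61657 non-control spots, 27265 (44.2%) were well above background on the PC-9 array and 26888 (43.6%) on the PC-9GR array. The 75th percentile of the signal was 232 intensity units for PC-9 and 209.6 for PC-9GR. Among 578 probes with at least 8 usable spots, the SD of replicate spots had a median of 0.07 on the log2 scale within each array. The SD of the difference between arrays over spots of the same probe had a median of 0.08 and a 95th percentile of 0.28. The 7 labelled spike-in probes measured on both arrays differed by -0.08 to 0.01, with a median of -0.05.

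The most prominent differences were genes that were bright in PC-9 and dim in PC-9GR. Transcripts of VCX2, a testis-associated gene of the X chromosome, were 89.2-fold lower in PC-9GR (log2 difference -6.48, technical SE 0.20), and those of S100P, a calcium-binding protein of epithelial tumours, were 76.6-fold lower (-6.26, SE 0.21). ADIRF was 33.7-fold lower, the secreted ribonuclease RNASE1 27.9-fold lower, the epidermal keratin KRT6A 27.4-fold lower and the tyrosine kinase SYK 16.5-fold lower. On the opposite side PALM, a membrane-associated phosphoprotein, was 8.46-fold higher in PC-9GR (log2 difference 3.08, SE 0.22), the collagen receptor MRC2 was 5.78-fold higher, and the fibroblast growth factor FGF2 was 4.50-fold higher over 2 probes (2.17, SE 0.20).

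In all, 15364 genes were well above background on both arrays, and their levels correlated with r = 0.979 across genes, which are not independent replicates. By the 2-fold threshold 255 genes were higher in PC-9GR and 432 were lower, together 687 genes or 4.47%. Genes apart by 4-fold or more numbered 19 higher and 76 lower. The size of the surplus of lower genes depended on the scaling. Genes higher in PC-9GR made up 37.1% of those apart in the main setting, 21.5% without scaling (159 higher, 580 lower), and 44.3% when the arrays were centred on the median difference of the spike-in probes (305 higher, 384 lower), a setting chosen after seeing the data. Centring on the median over all spike-in spots gave 50.9% (355 higher, 343 lower), with all genes shifted by 0.0889, and that median rests on the spots of 1 of the 7 measured probes. Background correction by normexp left 78 genes higher and 208 lower. Of 3416 genes with several probes, 1016 had probes that differed in direction. Among the genes apart by 2-fold, 91 had several probes, and in 4 of these the probes differed in direction.

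**Figure D1:**
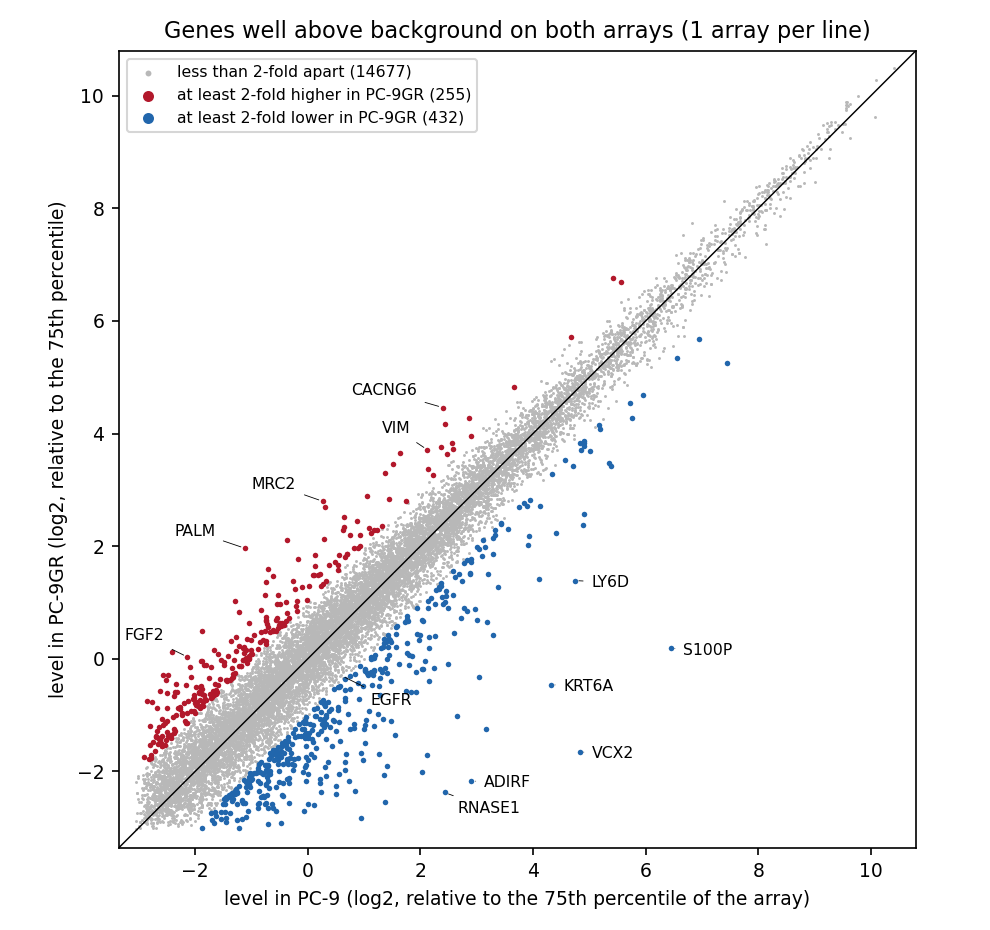
Scaled log2 level of each of 15364 genes on the PC-9 array (x axis) and the PC-9GR array (y axis), relative to the 75th percentile of each array, with the line of equal levels. Points are genes, red for the 255 at least 2-fold higher and blue for the 432 at least 2-fold lower in PC-9GR, and S100P, VCX2 and KRT6A lie far below the line.

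Other genes among the 15 with the largest differences in each direction covered several functions. Higher in PC-9GR were GFOD1 (5.54-fold), ZNF469 (5.26-fold), EEIG2 (4.89-fold), the Ras activator RASGRP1 (4.63-fold), EML1 (4.39-fold), PCOLCE2, which enhances procollagen processing (4.31-fold), SYDE2 (4.29-fold), STXBP6 (4.21-fold), CACNG6 (4.19-fold), the proteoglycan SPOCK1 (4.11-fold), the adrenergic receptor ADRA1B (4.08-fold) and the intermediate filament protein SYNM (3.999-fold). Lower were the G-protein subunit GNAO1 (15.1-fold), SLC37A2 (14.3-fold), the long non-coding RNA CRNDE (13.6-fold), ZG16B (12.6-fold), the keratin KRT6C (log2 difference -3.42), MFAP5 of elastic microfibrils (10.4-fold), the squamous surface marker LY6D (10.2-fold), the class II histocompatibility gene HLA-DQB1 (9.93-fold) and DDIT4L (9.07-fold). The technical SE of these differences ran from 0.07 for GFOD1 to 0.35 for SYDE2. On hg19 the probe for PALM lay on chromosome 19 from 748269 to 748328, that for MRC2 on chromosome 17 from 60770827 to 60770886, that for S100P on chromosome 4 from 6698819 to 6698878, and that for KRT6A on chromosome 12 from 52881087 to 52881146. KRT6A and KRT6C, and VCX2 and its relatives, are near-identical in sequence, so their probes may not tell family members apart.

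Genes of antigen presentation were lower in PC-9GR. Of the 20 members measured on both arrays 18 lay below 0, 5 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 difference of -0.70 (95% interval over members -0.99 to -0.26). That median was below those of all 10000 random lists matched on level. The class II genes HLA-DQB1 (-3.31), HLA-DRB1 (-2.42) and HLA-DMA (-1.97) had the largest differences, followed by the class I genes HLA-C (-1.21) and HLA-E (-1.08). The peptide transporter TAP2 differed by -0.99 and the immunoproteasome subunit PSMB8 by -0.96, whereas the class I regulator NLRC5 differed by 0.46 and the checkpoint ligand CD274 by 0.07. A further 5 members were detected on the PC-9 array only, among them CD74, the invariant chain (at least 3.59-fold), and CIITA, the class II transactivator (at least 3.70-fold). Detections on 1 array only, here and in the lists below, have a weak basis because isolated bright spots can produce them. Near-identical HLA genes can share signal on such probes. Markers of fibroblasts, endothelium and blood cells were lower alongside this list and the interferon and cytokine lists, with a median of -0.41 at the 0.96th percentile. All 6 measured members of 23 lay below 0, among them CSF1R (-0.75) and CD68 (-0.54). CD14 (-0.22, SE 0.27) and CD3D (-0.28, SE 0.40) differed by less than 1 technical SE. Of 23 lists placed 5 stood apart, where 1.15 would be expected by chance. A list near the limits, such as these markers or the cytokine list, therefore has a weak basis.

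Interferon-stimulated genes were also lower in PC-9GR. Of 23 measured members 19 lay below 0 and 5 were at least 2-fold lower, and the median was -0.42 (interval -0.71 to -0.20), at the 0.01th percentile of matched random lists. The antiviral GTPase MX1 was 3.92-fold lower, IFIT3 3.88-fold lower, IFI6 3.24-fold lower, ISG20 2.56-fold lower and OAS3 2.49-fold lower. IFITM1 lay in the opposite direction at 0.53. Inflammatory cytokine and NF-kB genes had a median of -0.23 (interval -0.52 to -0.02, 17 members) at the 1.14th percentile, with the cytokine IL32 at -1.21, the neutrophil chemokine CXCL8 at -1.05 and CXCL1 at -0.88, and the macrophage growth factor CSF1 in the opposite direction at 1.43. The placement of this list outside the central 95% was lost with normexp background correction and with the stricter filter on dim probes.

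Mesenchymal markers were the 1 list that stood apart in the opposite direction. Their median was 0.52 over 15 measured members of 27, at the 99.99th percentile of matched random lists. The interval over members ran from -0.40 to 0.76, and 10 members lay above 0 and 5 below, among them SNAI1 (-0.40). Another 11 genes of the list, such as ZEB1 and ZEB2, were detected on neither array. The intermediate filament vimentin (VIM) was 3.01-fold higher in PC-9GR (log2 difference 1.59, SE 0.20, probe on chromosome 10), N-cadherin (CDH2) was 2.23-fold higher and fibronectin (FN1) 2.05-fold higher. The calcium-binding protein S100A4 was 4.44-fold lower (-2.15), and TWIST1 was detected on the PC-9 array only, at least 1.69-fold. With no filter on dim probes the list no longer stood apart. Epithelial markers did not stand apart, with a median of -0.09 at the 6.54th percentile, and 0 of 28 were 2-fold apart. E-cadherin (CDH1) differed by 0.66 (SE 0.06) and desmoplakin (DSP) by 0.71, whereas claudin 1 (CLDN1) differed by -0.99 and the protease ST14 by -0.80.

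**Figure D2:**
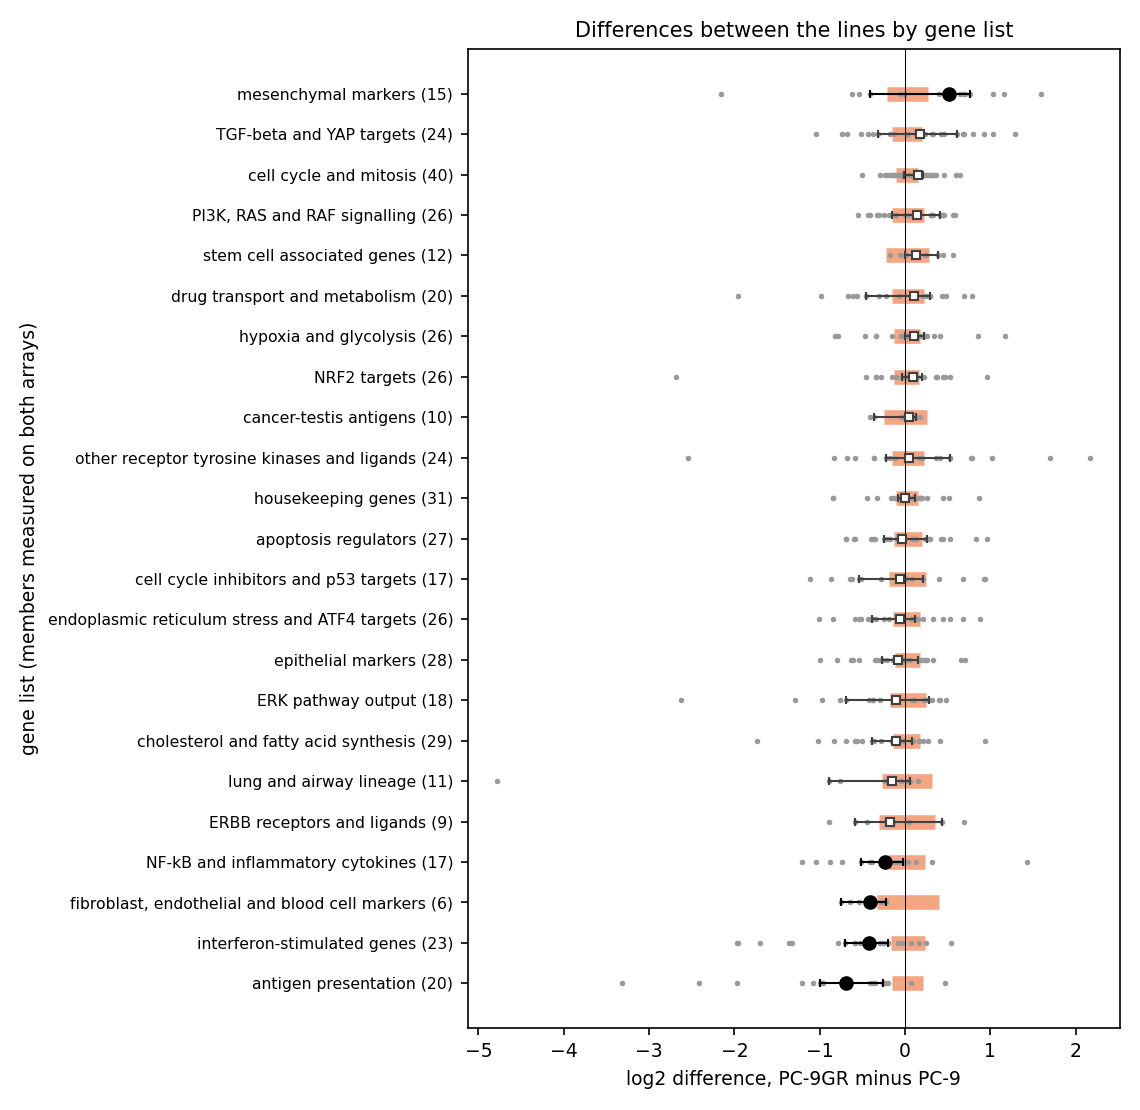
Log2 difference between PC-9GR and PC-9 (x axis) for 23 gene lists with the number of members measured on both arrays (y axis). Grey points are member genes, squares and circles are list medians with the 95% interval over members, orange bars hold the central 95% of 10000 matched random lists, and filled circles mark the 5 lists whose median lies outside that bar.

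**Figure D3:**
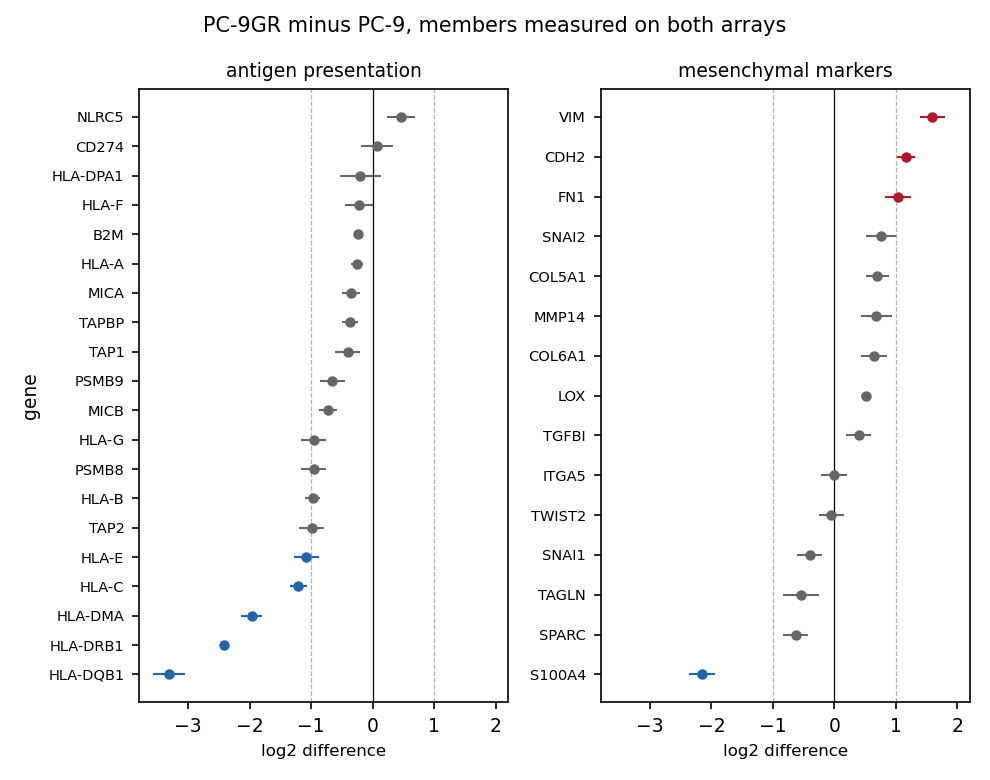
Log2 difference between PC-9GR and PC-9 (x axis) of each measured member of the antigen presentation and mesenchymal lists (y axis), with dashed lines at 2-fold. Bars are 1 technical SE on either side, from Agilent's spot error, and hold no variation between cultures, RNA preparations or labellings. Blue and red points are at least 2-fold lower and higher in PC-9GR, and 18 of 20 antigen presentation genes lie below 0.

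Transcripts of EGFR, the target of gefitinib, were 1.85-fold lower in PC-9GR over 3 probes (log2 difference -0.89, SE 0.14), with 1 of them on chromosome 7 from 55274841 to 55274900. The 3 probes all lay below 0 but ranged from -1.43 to -0.46, wider than the SE, which rests on Agilent's spot error only. The related receptor ERBB3 differed by 0.43 (SE 0.15). ERBB2 (0.05), MET (0.04) and AXL (0.04), receptors often studied in resistance to EGFR inhibitors, differed by less than 1 technical SE, and all 3 values are negative without scaling. The ERBB receptors and ligands had a median of -0.17 over 9 members, at the 9.85th percentile. Among other receptor tyrosine kinases and their ligands (24 members, median 0.04, 51.7th percentile), FGFR1 was 3.24-fold higher in PC-9GR over 1 probe, and KITLG was 2.02-fold higher, while IGFBP2 was 5.82-fold lower. The ligand FGF2 was also higher, but the receptors FGFR3 (-0.59) and FGFR4 (-0.36) lay below 0. FGFR2 was detected on the PC-9 array only (at least 2.05-fold). In the ERK pathway output list (18 members, median -0.11, 8.55th percentile) the phosphatase DUSP5 was 6.15-fold lower and MAFF 2.45-fold lower, SPRY2 differed by -0.97, and DUSP6 (0.22), CCND1 (0.42) and SPRY1 (0.48) lay above 0.

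None of the remaining signalling and survival lists stood apart. The PI3K, RAS and RAF list had a median of 0.15 over 26 members (87.9th percentile), with NRAS at 0.59 and MAPK3 at -0.43. The apoptosis regulators had a median of -0.03 over 27 members (21.8th percentile), with the pro-apoptotic BMF at 0.96, FAS at 0.83, BCL2L11, which encodes BIM, at 0.28 (SE 0.12), and BIK at -0.69. Cell cycle and mitosis genes had a median of 0.15 over 40 members, at the 97.46th percentile and so just inside the central 95%, with CENPF at 0.65, MCM6 at 0.60 and PLK1 at -0.51. They lay just outside with the loess trend removed, with the stricter filter and with the median of probes. Cell cycle inhibitors and p53 targets had a median of -0.06 (19.6th percentile), with CDKN1C at -1.12 and GADD45A at 0.94. TGF-beta and YAP targets had a median of 0.18 (95.9th percentile), with ID3 at 1.29, LTBP2 at 1.03 and ANKRD1 at -1.04.

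Metabolic and stress lists showed single genes apart within groups that did not stand apart. In the cholesterol and fatty acid synthesis list (median -0.11, 5.63th percentile) the SREBP-regulated INSIG1 was 3.34-fold lower in PC-9GR, while ELOVL6 lay at 0.93. The aldo-keto reductase AKR1B10 was 6.42-fold lower among the NRF2 targets (median 0.09, 81.0th percentile), where AKR1C1 lay at 0.96, and the aldehyde dehydrogenase ALDH3A1 was 3.87-fold lower in the drug transport and metabolism list (median 0.11, 77.5th percentile). The drug efflux pump ABCB1 was not well above background on either array. EGLN3, a hypoxia-inducible prolyl hydroxylase, was 2.26-fold higher in the hypoxia and glycolysis list (median 0.10, 81.5th percentile), and its difference was -1.24 with no filter on dim probes. CTH differed by -1.01 in the endoplasmic reticulum stress and ATF4 list (median -0.06, 14.2th percentile). Without scaling all genes shifted by -0.15, and the small positive medians of the NRF2, drug and hypoxia lists were then negative.

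Lineage markers were sparse. Of 25 lung and airway lineage genes 11 were measured on both arrays, with a median of -0.15 (10.71th percentile). Besides KRT6A, the basal keratin KRT5 was detected on the PC-9 array only, at least 11.1-fold. Only 2 of 14 neuroendocrine markers were measured, UCHL1 (-0.17) and ENO2 (-0.08), too few to place the list. Stem cell associated genes (median 0.13, 77.2th percentile) and cancer-testis antigens (median 0.05, 56.2th percentile) held 0 genes 2-fold apart among those measured on both arrays. Of the stem cell list, HEY1 (at least 3.37-fold) and SALL4 (at least 2.89-fold) were detected on the PC-9GR array only and WNT5A (at least 3.20-fold) on the PC-9 array only. These detections and that of KRT5 may be isolated bright spots. Only 6 of the 23 markers of fibroblasts, endothelium and blood cells were measured, with CDH5 at -0.65, and with no filter on dim probes their median was 0.0162, still below the central 95% of random lists. Housekeeping genes had a median of -0.00106 over 31 members (31.5th percentile).

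A separate set of genes was detected on 1 array only. With a bound of at least 2-fold there were 267 such genes on the PC-9GR array and 570 on the PC-9 array. The largest bounds on the PC-9GR side belonged to ANGPTL4, a secreted lipase inhibitor (at least 31.0-fold), LIG4 (18.0-fold), DCHS1 (16.8-fold), HTR6 (15.3-fold), KANK4 (14.999-fold), P2RX7 (14.2-fold), EPHA5 (12.2-fold) and TARS3 (11.8-fold). Those on the PC-9 side belonged to thrombomodulin, THBD (at least 31.3-fold), AGTR2 (25.5-fold), CTAGE10P (21.4-fold), CCDC102B (19.4-fold), the cornified envelope gene SPRR2E (19.1-fold), HLA-DRB5 (18.9-fold), TRPM2 (18.8-fold) and the olfactory receptor OR2B11 (18.6-fold). All of these except KANK4 rest on 1 probe. Counting only genes whose bright side rested on replicated spots or several probes, a restriction chosen after seeing the data, left 13 on the PC-9GR array and 22 on the PC-9 array. Probes for synthetic RNAs that are no part of the human transcriptome were well above background on 119 of 3360 spots on the PC-9 array and 101 of 3360 on the PC-9GR array, so single genes in this set have a weak basis.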

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

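The test of detection shared by the probes of a gene, and the test restricted to bounds of at least 2-fold, were chosen only after the results had been seen. The number of bright control spots had also been seen when the other tests were set. Outside the gene probes, each array carries 3360 spots of 96 probes for ERCC RNAs, synthetic controls that are no part of human RNA. On the PC-9 array 119 of them (3.54%, 95% exact Clopper-Pearson interval 2.94 to 4.22) were well above background, and on the PC-9GR array 101 (3.01%, 2.45 to 3.64), where the limit that a count of 0 allows is 0.0893%. Only 1 and 2 of the 96 probes, respectively, were bright on the majority of their spots. Isolated spots, those of the other probes, made up 85 of the 119 bright spots on the PC-9 array but 31 of the 101 on the PC-9GR array. Among the 308 negative-control spots of each array, 4 (1.30%, 0.355 to 3.29) were well above background on the PC-9 array and 5 (1.62%, 0.529 to 3.75) on the PC-9GR array, against a limit of 0.974% for a count of 0. The intervals cover counting error only.

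These spots bear on the genes detected on 1 array only. If dark gene probes with 1 spot lit up as often as ERCC spots, they would give 78.9% of the 1046 such probes with a bound of at least 2-fold (825 expected, bootstrap interval over ERCC probes 52.1 to 119.8), so isolated bright spots may account for most of that set. By array, 489 were expected against 686 seen on PC-9, and 336 against 360 on PC-9GR. On the PC-9GR array 38 ERCC spots with such a bound set the rate, but only 31 bright ERCC spots were isolated. The rate thus includes spots of probes bright on most of their spots. The number expected there, and with it the share of 78.9%, is therefore too high for isolated spots alone. Without the bound the ERCC rates would give 40.3% of 2819 probes (27.4 to 60.6), too few to be the whole account of the fainter detections. Bright ERCC spots had a neighbour above the 95th percentile of all spots 0.999 times as often as other ERCC spots (interval 0.875 to 1.14). The shares were 50.9% and 51.0%, so bright ERCC spots showed no excess of such neighbours. With so high a share among the other spots, the ratio set beforehand for this cause could not be reached. The test therefore cannot exclude light from bright neighbours. Expression that differs between the lines stays open: other probes of the same gene pointed the same way in 50.5% of 640 genes, but 94.0% of those probes were dark on both arrays. Of all probes dark on both arrays 80.8% lie above 0, for a reason that was not tested. Signs of dark probes thus lean 1 way, so the limit set beforehand for this test was wrong. The other probes were well above background on the same array in 61 cases against 50.7 predicted from all gene probes (ratio 1.203, interval 0.926 to 1.53).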

How the results depend on the processing

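Each line has 1 array, so no array could be left out. No paired analysis was possible because there is 1 array per line and the result comes from no test. Chosen after seeing the data were the restriction to replicated measurements, the GC correction and centring on the median of spike-in probe differences. The antigen presentation and interferon lists stood apart in all 16 alternatives, with medians from -0.85 to -0.61 and from -0.59 to -0.24. Genes at least 2-fold higher and lower in PC-9GR numbered 255 and 432. They numbered 78 and 208 with normexp, 58 and 112 with the stricter filter on dim probes, 1556 and 1871 with no filter, 19 and 76 at 4-fold, 1260 and 1258 at 1.5-fold, and 50 and 67 over the 3853 genes with replicated measurements (3.04% of them). Without scaling 159 were higher. A higher threshold lowers a count by construction and a lower threshold raises it. The offset of 50 in normexp draws differences of dim spots towards 0. The filters change which genes are counted. With the stricter filter 1.99% of 8525 genes were apart and with no filter 9.46% of 36230, against 4.47% of 15364. How much of each change these steps explain was not tested. Genes detected on the PC-9GR array only (267) numbered 98 with normexp, 98 at 4-fold, 497 at 1.5-fold and 13 with replicated measurements. Those on the PC-9 array only (570) numbered 218, 246 at 4-fold and 22 with replicated measurements. Without scaling, which shifts all genes by -0.15, the list medians were -0.0544 for NRF2 targets, -0.0431 for hypoxia and glycolysis, -0.0191 for stem cell associated genes and -0.15 for housekeeping genes. Centring on the median over spike-in spots gave 0.24 for cell cycle and 0.14 for cancer-testis antigens. With no filter on dim probes the fibroblast, endothelial and blood cell list turned to 0.0162 and EGLN3 to -1.24, as probes at background then enter. The cholesterol list stood apart with quantile normalisation and the GC correction only. Of 2719 values of 189 named genes under the alternatives, 2533 stayed within 1 technical SE and 185 moved further. Bounds were judged by the median technical error. In 1 value a difference of at least 2-fold reversed its sign. Sign changes of smaller differences, such as those of ERBB2, MET and AXL without scaling, were not counted as reversals. Part of this stability was built in. The shift of -0.15 without scaling is smaller than the median technical SE of 0.208. A gene with 1 probe keeps its value under both other probe rules, and the series value table held the same intensities. Of 77 named genes apart by 2-fold, 16 were no longer apart in at least 1 alternative. With under 5 members measured, the lung and fibroblast lists gave no value under the stricter filter.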

Other observations

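Of the tests below, the one by blocks of the array was chosen only after the result was seen. Beyond the lists of the report, genes of squamous epithelium were lower in PC-9GR. KRT6A, KRT6C, LY6D and SPRR2E had been noticed among the largest differences, and a list of 56 other squamous genes was then written without them. Of 31 measured members 27 lay below 0, 11 were at least 2-fold lower and 0 at least 2-fold higher. They included the cornified envelope genes SPRR3 (-2.40), SPRR1B (-1.80) and SPRR1A (-1.66), the calcium-binding proteins S100A14 (-2.34) and S100A9 (-1.73), and the keratins KRT6B (-1.38) and KRT16 (-1.36), while LYPD3 (0.59) and SERPINB5 (0.46) lay above 0. The median of -0.39 (interval over members -1.36 to -0.17) was at percentile 0 of 10000 random lists matched on level, which is consistent with a wider squamous programme that is lower in PC-9GR, as a hypothesis from 1 array per line. A further 6 members, such as KRT13 (at least 9.04-fold) and KRT17 (at least 5.98-fold), were detected on the PC-9 array only and 1, PKP1, on the PC-9GR array only. Isolated bright spots may account for such detections, so they add little. The SPRR and keratin genes are families of similar sequence, so these members are not independent. Random lists were matched on level and not on chromosome position, so any members that lie close together may also shift together.

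Genes also differed by chromosome region. Over 15274 genes placed on hg19, medians of 40 genes in a row, relative to the median of all genes, marked 6 higher and 14 lower regions. The largest higher region, on chromosome 1 from 71.5 to 143.4 Mb, had 182 of 224 genes in that direction, among them SYDE2 (2.10), MCOLN3 (1.94) and ARHGAP29 (1.71), while ST6GALNAC5 (-2.19), SLC16A4 (-1.73) and ABCA4 (-1.64) lay the other way. A higher region on chromosome 17 (49.2 to 75.6 Mb, 155 of 192 genes) held MRC2 (2.53) and PRKCA (1.23). A lower region on chromosome 11 (85.99 to 134.6 Mb, 182 of 214 genes) held CASP1 (-2.63), CASP5 (-1.14) and CASP4 (-1.02), and one on chromosome 5 (0.205 to 52.9 Mb, 101 of 125 genes) held DAB2 (-1.92) and OSMR (-1.05). These genes were chosen after their values were seen. The regions were marked by medians of the same gene differences, so a majority of genes in each region's own direction was built in. The counts of genes in that direction therefore give no evidence of a shift beyond those medians.

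Chance arrangement is argued against, because the largest absolute median was 0.738, on chromosome 1 from 91.25 to 97.54 Mb, against a highest value of 0.394 over 1000 shuffled gene orders. Probe GC content is argued against for that window, whose median stayed at 0.708 after a GC trend was removed (95th percentile of shuffled orders 0.322), but of the 20 regions that on chromosome 14 was lost and that on chromosome 16 from 23.7 to 30.6 Mb was not kept as such, so GC content stays open there. The mean array row of genes in the regions differed from that of other genes by 1.21% of the array, which decides nothing because regions that shift both ways are pooled. With the median of each of 100 blocks of the array taken off, the largest median was 0.745 (highest shuffled value 0.404) and 18 of the 20 regions kept a window above the 95th percentile of shuffled orders, which argues against array position for these. A candidate explanation is that the lines differ in the copy number of these regions, which expression arrays do not measure and which was not tested.

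The lower antigen presentation genes lie mostly in 1 such region. A trend of the difference with signal level is argued against, since the list median was -0.74 (interval -1.05 to -0.30) after that trend was removed. Shared signal between near-identical HLA genes cannot be told apart, because the 10 members that are not HLA genes had a median of -0.39 but an interval from -0.96 to 0.07. Loss of the region may contribute but is not settled: 121 other genes of chromosome 6 from 29 to 34 Mb, without HLA and MIC genes, had a median of -0.26 (interval -0.33 to -0.18), between the values set beforehand for and against it, while the 17 list members in that region had a median of -0.96. The 3 measured members elsewhere, B2M (-0.24), CD274 (0.07) and NLRC5 (0.46), are too few to separate the region from the function, and a regulated difference between the lines stays open.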
